A study of Mus musculus with 24 samples.

How the data were processed

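Bulk RNA sequencing was analysed for 24 mouse libraries of sorted tissue-resident macrophages. The labels divide them into 8 groups of 3: alveolar macrophages of the lung, Kupffer cells of the liver, microglia of the brain and splenic macrophages, each from wild-type (WT) animals and from the genotype Z165KO (KO here). Per the labels' protocols, RNA came from 100000 sorted macrophages per sample, was isolated with the NucleoSpin RNA XS kit, made into libraries with the SMARTer Ultra Low kit and sequenced on a NovaSeq X Plus. The labels do not say what gate was used for sorting or whether the kit and the counting kept strand, and they do not describe the Z165KO allele. Every sample was grouped by the cell type and genotype given in its own labels, and the replicate number came from its title.

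The authors deposited a table of the whole series with gene counts, counts scaled to the library total (CPM) and length-scaled transcript abundance (TPM) for each library. Per the submitters' processing notes, the build was mm10 and the tools named were DRAGEN, STAR, Subread, featureCounts and Salmon. Those notes as used here give neither the role nor the version of each tool, so how multi-mapping or overlapping reads were counted is not given in the sources used here. The deposited counts were whole numbers and not normalized, and every test was run on them. The deposited CPM values differed from CPM recomputed from the counts by at most 4.7e-11. The deposited TPM values were not used in any test, and for 4 of these deposited columns (splenic WT replicate 3 and the 3 splenic KO replicates) repeated rows took the column sum above 1000000. The table held 55774 rows, of which 287 repeated an earlier gene with identical values and were dropped, leaving 55487 genes. No row lacked a gene identifier and 0 value columns were left unused. Gene coordinates are 1-based and came from the GENCODE annotation of the mm10 build, in which 55227 of these genes (99.53%) were found.

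Total counts per library ranged from 50449347 to 65981787, and the largest ratio between totals within a cell type was 1.23. No pair of replicates agreed within sampling noise: the smallest chi-square per degree of freedom between replicates of a group was 32.7, so each library was counted as 1 replicate. Reads carried no molecular identifiers, so intervals and floors from counts cover counting error only. Where all 3 libraries of a group had 0 counts, a fold was computed against 3 counts over the group (0.0169 CPM in alveolar KO, 0.016 CPM in Kupffer KO and 0.0176 CPM in splenic KO) and is written as a lower bound. Where a group held 1 to 3 counts, the CPM values are given without a fold, because a fitted fold change there depends on the prior count.

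For each cell type, KO was compared with WT in its own 6 libraries with the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and the filterByExpr filter with a minimum count of 10. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values are from this test unless another is named. Fold changes are KO over WT on the log2 scale with their standard error (SE), and group values are mean CPM ± SD of 3 libraries. The difference of the genotype effect between cell types (an interaction F test) and the mean effect over the 4 cell types were tested in a single fit of all 24 libraries. The labels do not say whether libraries with the same number came from 1 animal, and this fit and the overlaps between cell types treat them as independent. The 12 WT libraries were compared with an F test, and identity genes with the contrast of each cell type against the mean of the other 3. With 3 libraries against 3, an exact two-sided permutation test of a single value cannot go below 0.1, so no such test was used.

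There were 40 gene lists (cell identities, markers of other cell types, pathways, and Zeb2 with genes near it and Zeb1), which were fixed before the data were examined. The main tests and the rule for naming genes were fixed then too. That plan did not name the contrast of the alveolar genotype effect with the mean of the other 3 types, or the adjustment of Zeb2 over the 4 cell types. Nor did it name the overlaps of called genes between cell types or the window of 5 Mb around Zeb2. A list was tested where at least 5 of its genes were tested, which left out the sex-linked list in all 4 cell types. Lists were tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a cell type, and again with an estimated correlation and with fry. Camera compares a list with all other genes, so a list can pass without any called member. Within each list, members were also counted after adjustment over the list alone. Genes named in the text were Zeb2 and the other members of its list. Among called genes with non-overlapping groups and at least 5 CPM in the higher genotype, the 8 highest and 8 lowest fold changes were added. Up to 4 members with the smallest p of each list described, genes called in at least 3 cell types, and the top 10 genes of the interaction and common tests completed the rule. Predicted genes, pseudogenes and immunoglobulin segments were only counted. Some genes that the rule takes are not reported here. Other genes named in the text are said to have been chosen after their values were seen.

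Alternatives tried were DESeq2 size factors and upper-quartile scaling, no filter and a stricter filter (mean of at least 1 CPM and 10 counts in at least 3 libraries), DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, a fold threshold of 1.5 (glmTreat), all 24 libraries in a single fit, and leaving out each library in turn. Removing immunoglobulin, T cell receptor and B lineage genes was an alternative chosen after seeing the data. The pipeline was tested on simulated counts drawn from the real means and library sizes. Of 100 genes changed 2-fold and 100 changed 4-fold, it called 45 and 88 in alveolar macrophages (16443 genes, 6 false calls), 35 and 85 in Kupffer cells (18125 genes, 6 false calls), 45 and 95 in microglia (16958 genes, 6 false calls) and 49 and 89 in splenic macrophages (16929 genes, 9 false calls). The interaction test recovered 82 of 100 genes changed 4-fold in alveolar macrophages alone (22652 genes, 3 false calls). The test of the common effect recovered 100 of 100 genes changed 4-fold in all 4 cell types. It called 174 genes, of which 15 were false calls of unchanged genes, and the remaining calls were genes changed in alveolar macrophages alone. A call of the common effect therefore does not show a change shared by the cell types.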

Results

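Gene expression was measured by bulk RNA sequencing in macrophages sorted from 4 mouse tissues: alveolar macrophages, Kupffer cells, microglia and splenic macrophages. Each was taken from WT animals and from the KO genotype, with 3 libraries in each of the 8 groups. Total counts per library ranged from 54136122 to 61036591 in alveolar macrophages and from 57733667 to 65981787 in Kupffer cells. They ranged from 50449347 to 55249334 in microglia and from 51613880 to 63234480 in splenic macrophages. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. The first 2 principal components of all 24 libraries held 30.3% and 21.5% of the variance.

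The WT libraries carried the genes by which the 4 macrophage types are usually told apart. Chil3, a chitinase-like protein secreted in the alveoli, stood at 20400 ± 2630 CPM in alveolar macrophages (SD, n = 3) and at 2.87 CPM in the mean of the other 3 types. Clec4f, a lectin of Kupffer cells, stood at 9350 ± 781 CPM against 0.116. Tmem119, a microglial membrane protein, stood at 4980 ± 520 CPM against 7.74, and Spic, a transcription factor of red pulp macrophages, at 1480 ± 150 against 45.7. Against the mean of the other 3 types, all 28 tested alveolar identity genes, all 24 Kupffer genes, all 25 microglial genes and 18 of 20 splenic genes were higher in their own type. The splenic exceptions were Siglec1 (adjusted p = 0.0532) and Ednrb (adjusted p = 0.0829). By the same contrasts, 17 of 20 splenic genes were also higher in Kupffer cells, and 16 of 24 Kupffer genes in splenic macrophages. Across the 12 WT libraries, 11331 of 21679 genes (52.3%) differed between the cell types.

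Zeb2 encodes a zinc-finger transcription factor that binds E-box motifs, and the series title names it together with cMaf, so it was read first in every library. In alveolar macrophages all 3 KO libraries lay below all 3 WT libraries, at 139, 126 and 142 CPM against 297, 282 and 190. The KO mean was 53% of the WT mean (136 ± 8.7 against 256 ± 57.7 CPM), with a log2 fold change of −0.89 ± 0.19 (SE; 95% interval −1.33 to −0.45). Its unadjusted p of 0.0019 from edgeR gave an adjusted p of 0.116 over all genes, so the gene was not called, and 0.0076 over the 4 cell types. DESeq2 called it (adjusted p = 0.000513), as did the fit of all 24 libraries (adjusted p = 0.0408). The adjusted p ranged from 0.000513 to 0.383 over all alternatives. In the other 3 cell types the genotypes overlapped. Kupffer cells had 277, 321 and 235 CPM in WT and 279, 237 and 282 in KO (log2 −0.04 ± 0.17; interval −0.43 to 0.36). Microglia had 329, 171 and 276 CPM in WT and 334, 249 and 263 in KO (0.12 ± 0.25; −0.45 to 0.70). Splenic macrophages had 330, 296 and 305 in WT and 322, 320 and 318 in KO (0.09 ± 0.09; −0.13 to 0.30). The sign in Kupffer cells turned without KO replicate 2 (0.08) or WT replicate 2 (0.09), and in microglia without KO replicate 1 (−0.01) or WT replicate 2 (−0.12). A difference of the Zeb2 effect between the cell types was not called (interaction adjusted p = 0.255, range over alternatives 0.0564 to 0.494). The alveolar effect differed from the mean of the other 3 by −0.95 ± 0.24 (adjusted p = 0.0737). Counts over the whole gene do not show whether a regulatory element or an exon was altered.

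**Figure D1:**
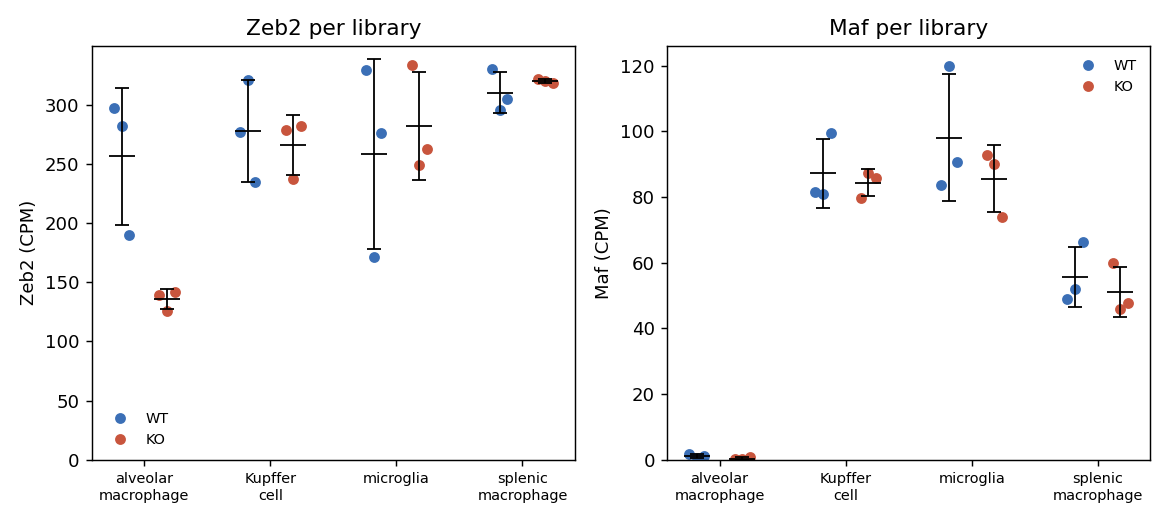
CPM (vertical axes, linear, starting at 0) of Zeb2 and Maf in each of the 24 libraries, by cell type and genotype; points are libraries, horizontal lines means and bars SD of 3 libraries. The 3 alveolar KO libraries lie at 126 to 142 CPM of Zeb2 and the 3 alveolar WT libraries at 190 to 297, while the genotypes overlap in Kupffer cells, microglia and splenic macrophages.

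Zeb2 (ENSMUSG00000026872) lies on the minus strand of chromosome 2 from 44983632 to 45117395 (mm10), and the antisense gene Zeb2os lies inside it from 45110707 to 45114087. Strand is not stated for the counting, so reads of Zeb2 and Zeb2os in the shared stretch cannot be told apart. Zeb2os read 1.49 ± 0.216 CPM in WT and 0.585 ± 0.232 in KO alveolar macrophages (adjusted p = 0.35). The fit of all 24 libraries called this difference (log2 −1.33 ± 0.31; adjusted p = 0.037). Microglia held 17.7 and 12.7 CPM (adjusted p = 0.987). In Kupffer cells it read 5.24 and 5.47 CPM, and in splenic macrophages 6.22 and 5.38. Of the 17 genes tested within 5 Mb on each side of Zeb2 in alveolar macrophages, 1 was called. This was Arhgap15 (chromosome 2, 43748824 to 44395953), a GTPase-activating protein for Rac, which fell from 18.9 ± 5.1 to 3.84 ± 0.565 CPM (log2 −2.27 ± 0.27; adjusted p = 0.0263). Its call was lost in each of the 6 fits that left out 1 alveolar library (adjusted p from 0.051 to 0.181). The same gene stood at 54.3 CPM in WT and 40.2 in KO splenic macrophages (adjusted p = 0.272), and its effect differed between cell types (interaction adjusted p = 0.00676). None of the 20, 18 and 18 genes tested around Zeb2 in Kupffer cells, microglia and splenic macrophages was called. The list of Zeb2, genes near it and its paralogue Zeb1, which lies on chromosome 18, had 7 genes tested in alveolar macrophages and was shifted downwards (median log2 −0.40; adjusted p = 0.049), with 0 rising and 1 falling, and 0 and 2 after adjustment over the list alone. With an estimated correlation the adjusted p was 0.295, and the call was also lost without KO replicate 1 (0.0944), 2 (0.106) or 3 (0.116) and without WT replicate 2 (0.0842) or 3 (0.0618). Its other members in alveolar macrophages had log2 fold changes of −0.40 (Acvr2a; adjusted p = 0.522), −0.16 (Kynu; 0.736), 0.28 (Gtdc1; 0.816) and 0.22 (Zeb1; 0.776).

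Maf, the gene of cMaf, was chosen for naming because the title names cMaf, and no difference was called. Maf read 1.2 CPM in WT and 0.388 in KO alveolar macrophages (adjusted p = 0.522), 87.3 and 84.3 CPM in Kupffer cells, 98.1 and 85.6 in microglia, and 55.7 and 51.1 in splenic macrophages. In the fit of all 24 libraries the alveolar log2 fold change was −1.62 ± 0.44 (adjusted p = 0.0865), and it differed from the mean of the other 3 types by −1.52 ± 0.48 (adjusted p = 0.17).

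The next comparison asked which transcripts differed between genotypes in libraries of alveolar macrophages, the cells that clear surfactant and particles from the airspace. KO libraries had more transcript of Il1f9, which encodes the inflammatory cytokine IL-36γ, and of Cxcr2, a chemokine receptor best known from neutrophils. Myo1d, a class I myosin, and the lysosomal tetraspanin Cd63 were higher too. Lower in KO were Emilin1, a glycoprotein of elastic fibres, and Slc16a1, a lactate and pyruvate transporter. So was Adgre4, an adhesion receptor of the EGF-TM7 family. For Cxcr2, more neutrophils carried through the sort cannot be told apart from a change in the macrophages, and for Adgre4 carry-over was not tested. Transcripts of B cells (Fcer2a, Fcmr) and of Cd209a, a lectin of monocyte-derived and dendritic cells, almost vanished. Of 17369 genes tested, 55 were called, 32 higher and 23 lower in KO, and 2172 had an unadjusted p under 0.05. No called gene had overlapping groups. Chance leaves 10% of all genes without overlap at 3 against 3, but a call itself makes this likely, so it adds no support. Without KO replicate 2 or WT replicate 2 no gene passed. Without WT replicate 1, KO replicate 3, WT replicate 3 or KO replicate 1 there were 3, 8, 19 and 29. The replicate block also left 0, the fit of all 24 libraries called 297 and DESeq2 called 922.

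Among the genes that rose in alveolar macrophages, Il1f9 (chromosome 2, 24186476 to 24193568) went from 3.76 ± 1.52 CPM in WT to 65.1 ± 16.6 in KO, a 17.3-fold difference (adjusted p = 0.00885). Myo1d (chromosome 11, 80482126 to 80780025) rose 13.1-fold, from 4.99 ± 1.64 to 65.3 ± 8.47 CPM (log2 3.75 ± 0.25; adjusted p = 0.00846), and the neighbouring gene Tmem98 (80810175 to 80822033) rose from 0.791 to 9.12 CPM (adjusted p = 0.0258). Cxcr2 (chromosome 1, 74153989 to 74161246) rose 6.18-fold, from 17.7 ± 5.07 to 110 ± 8.58 CPM (log2 2.67 ± 0.21; adjusted p = 0.00885). Cd63 went from 73.6 ± 9.23 to 345 ± 77 CPM (4.68-fold; adjusted p = 0.00846). Card14, a scaffold of NF-κB signalling, was close to absent in WT at 0.0233 CPM and reached 5.04 ± 1.37 in KO (adjusted p = 0.0254). Mustn1 rose from 0.88 to 8.65 CPM, Mfsd6 from 6.9 to 42.1, and Basp1, a membrane-bound protein of the cell cortex, from 18.3 ± 5.73 to 110 ± 10 CPM. Bmpr1a, a receptor for bone morphogenetic proteins, rose from 6.79 ± 0.558 to 22.2 ± 5.61 CPM (adjusted p = 0.0493), a call that was lost with DESeq2 size factors.

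Among the genes that fell in alveolar macrophages, Emilin1 (chromosome 5, 30913402 to 30921277) went from 244 ± 41.8 to 17.7 CPM, 13.7-fold lower (log2 −3.76 ± 0.42; adjusted p = 0.0258). Adgre4 went from 9.7 ± 1.1 to 0.033 CPM, 294-fold lower (adjusted p = 0.0346). Slc16a1 fell from 29.3 ± 6.16 to 5.66 ± 0.818 CPM (log2 −2.35 ± 0.23; adjusted p = 0.0233). Klk8, a secreted protease, fell from 8.16 to 0.56 CPM. Retnla, a marker of alternative activation, fell from 11.3 to 0.828 CPM, and Gpd1, a glycerol-3-phosphate dehydrogenase, from 20.8 to 1.76. Cd209a (chromosome 8, 3743397 to 3748984) stood at 14.8 ± 7.23 CPM in WT and at 0.00546 in KO, which is a single read over the 3 libraries (adjusted p = 0.00846).

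**Figure D2:**
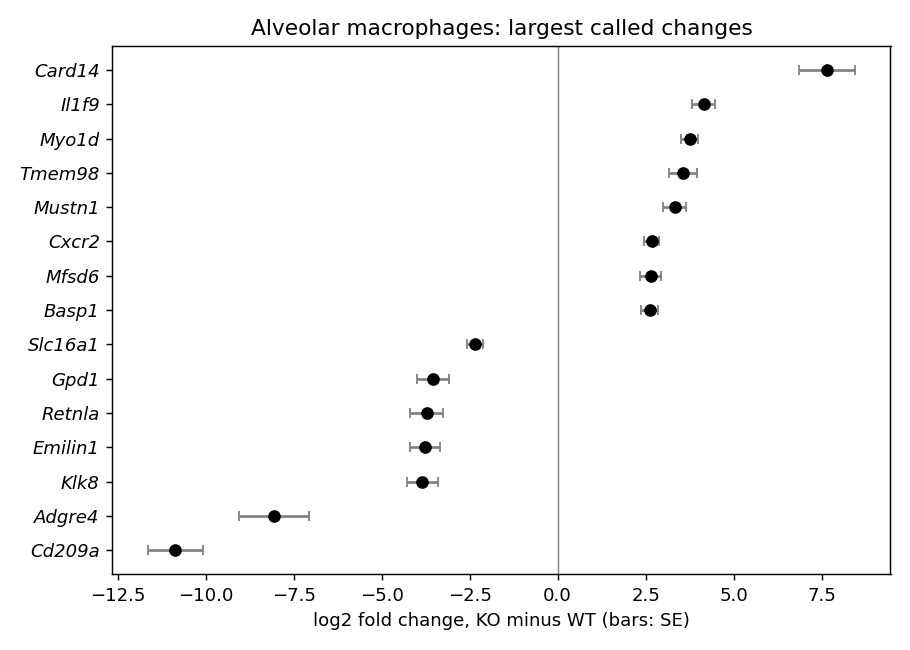
Log2 fold change of KO over WT (horizontal axis; points are fitted values, bars SE) for genes among the 8 highest and 8 lowest called in alveolar macrophages, 3 libraries in each genotype. Values run from 7.65 for Card14 to −10.86 for Cd209a; that of Cd209a rests on 1 KO read and depends on the prior count.

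Of the 38 lists tested in alveolar macrophages, 13 passed, 8 upwards and 5 downwards. None of them passed with an estimated correlation, where the smallest adjusted p was 0.0551, while fry called 12. The group with the largest change was the list of B cell markers, of which 3 of 13 tested members fell and none rose, and 11 fell when adjusted over the list alone. Its median log2 was −5.79, or −5.04 with genes at 0 in KO set to their bound (adjusted p = 3.23e-19, and adjusted p = 0.0551 with an estimated correlation). Fcer2a, the low-affinity IgE receptor, went from 2.93 to 0 CPM, at least 174-fold lower. Ighm, the IgM heavy chain, fell from 75.9 ± 42.9 to 7.47 ± 1.05 CPM (adjusted p = 0.0258). Fcmr, the Fc receptor for IgM, went from 4.04 to 0.00546 CPM.

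Markers of other myeloid cells moved apart from one another in the alveolar libraries. Of 18 monocyte markers 0 rose and 1 fell, and 0 and 8 adjusted over the list alone. The list was shifted downwards (median log2 −1.04; adjusted p = 0.000709, and adjusted p = 0.255 with an estimated correlation), and its summed level was 2330 CPM in WT and 1440 in KO. Ms4a6c, a membrane protein of monocytes, fell from 13 to 2.94 CPM (adjusted p = 0.0346), while Fn1, F13a1 and Ms4a4c had log2 fold changes of −1.22 (adjusted p = 0.115), −1.31 (0.16) and −3.08 (0.11). Of 13 neutrophil markers 1 rose and 0 fell, and 3 and 0 adjusted over the list alone. This list was shifted upwards (median log2 1.07; adjusted p = 6.47e-05, and adjusted p = 0.295 with an estimated correlation). The called member was Cxcr2, while the granulocyte colony-stimulating factor receptor Csf3r read 122 and 248 CPM (adjusted p = 0.0811). The calprotectin genes S100a9 and S100a8 read 63.9 and 131 (0.206) and 47.5 and 80.1 (0.291). Border-associated macrophage genes had all 13 tested members below 0 and none called, in either count. They were shifted downwards as a list (median log2 −0.90; adjusted p = 0.000709, and adjusted p = 0.295 with an estimated correlation). Mgl2, a lectin of this list, read 22.6 CPM in WT and 4.19 in KO (adjusted p = 0.203). Basophil, mast cell and eosinophil markers were shifted upwards (7 tested, 1 rising in both counts; adjusted p = 0.0109, and adjusted p = 0.275 with an estimated correlation). The called member was Ear6, an eosinophil-associated ribonuclease, which rose from 4.12 to 23.3 CPM (adjusted p = 0.0432). That list call was lost without KO replicate 1 (0.0735), 2 (0.156) or 3 (0.243) or WT replicate 2 (0.201). Endothelial markers (13 tested, 0 called in either count; median log2 0.35; adjusted p = 0.0258, and adjusted p = 0.559 with an estimated correlation) lost theirs without KO replicate 1 (0.157), 2 (0.156) or 3 (0.0516) or WT replicate 1 (0.077) or 3 (0.565). Dendritic cell markers did not pass (17 tested, 1 falling, adjusted p = 0.399), and their median of 0.07 and mean of −0.71 differed in sign.

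Lists of LXR targets and lipid efflux, of the lysosome and autophagy, of glycolysis and of oxidative phosphorylation were shifted upwards in the same alveolar libraries. The KO libraries also held fewer genes at 10 or more counts (15958 to 17171, against 17436 to 18514 in WT). Their 10 most abundant genes took 11.49% to 12.04% of counts, against 9.54% to 10.56% in WT. Whether these differences bear on the list shifts was not tested. Cholesterol biosynthesis did not pass (adjusted p = 0.854; median log2 −0.09). LXR target and lipid efflux genes had 0 called of 16, and 5 rising and 0 falling when adjusted over the list alone. Its median log2 was 0.18 (adjusted p = 0.00455, and adjusted p = 0.258 with an estimated correlation), while its summed level was 5140 CPM in WT and 4910 in KO. Scd1, a fatty acid desaturase, read 27.3 CPM in WT and 80.2 in KO (adjusted p = 0.188), and Nr1h3, which encodes LXRα, 60.4 and 107 (adjusted p = 0.0811). Lysosome and autophagy genes had 0 called of 28, and 5 rising and 1 falling over the list alone (adjusted p = 0.00978, and adjusted p = 0.258 with an estimated correlation). Gpnmb, a lysosomal glycoprotein, read 762 and 1580 CPM (adjusted p = 0.0503). Glycolysis genes had 0 called of 19 and 3 rising over the list alone (adjusted p = 0.0166, and adjusted p = 0.295 with an estimated correlation; 0.0586 without KO replicate 2). The glucose transporter Slc2a1 read 32.4 and 75.7 CPM (adjusted p = 0.0582). No member was called in either count among 24 oxidative phosphorylation genes (median log2 0.10; adjusted p = 0.0161, and adjusted p = 0.559 with an estimated correlation; 0.0551 without KO replicate 2 and 0.222 without WT replicate 1). The same held for 32 cytosolic ribosomal proteins (median log2 0.18; adjusted p = 0.000709, and adjusted p = 0.591 with an estimated correlation; 0.199 without WT replicate 1). Inflammatory cytokines and chemokines were shifted downwards, with 0 called of 24, and 1 rising and 4 falling over the list alone. Its median log2 was −1.30 (adjusted p = 0.00253, and adjusted p = 0.559 with an estimated correlation; 0.0936 without WT replicate 2). Ccl3, Ccl7 and Ccl2, chemokines that attract leukocytes, read 172 and 56.2 CPM (adjusted p = 0.0884), 10.2 and 2.37 (0.0935) and 26.4 and 11.5 (0.16), while Ccl6 read 4730 and 6820 (0.159). Dissociation stress and immediate early genes did not pass in these libraries (0 called of 21, and 0 rising and 2 falling over the list alone; median log2 −0.59; adjusted p = 0.0879), and 18 of them had fitted values below 0. Their sum was 19900 CPM in WT and 10900 in KO.

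Some lists that did not pass in alveolar macrophages held called members. Of 21 tested epithelial genes that ZEB factors are known to repress, 3 rose and 0 fell, and 5 and 1 after adjustment over the list alone (list adjusted p = 0.0879, and adjusted p = 0.419 with an estimated correlation). Cdh1, which encodes E-cadherin, rose from 120 ± 4.88 to 226 ± 37.1 CPM (log2 0.94 ± 0.12; adjusted p = 0.0402). Tjp3, a tight junction scaffold, rose from 3.5 to 15.9 CPM (adjusted p = 0.0481), and St14, a membrane-anchored serine protease, from 3.3 to 13.2 (adjusted p = 0.0483). Epcam read 87.4 and 233 CPM (adjusted p = 0.104). In iron and heme handling, 2 of 18 rose, and 4 rose and 1 fell over the list alone (list adjusted p = 0.0879). They were the ferritin heavy chain Fth1, from 13100 ± 959 to 18700 ± 377 CPM (adjusted p = 0.0402), and the biliverdin reductase Blvrb, from 40.9 to 76.9 (adjusted p = 0.0391). Fth1 was not called without the filter on low counts. Pdk4, which restrains pyruvate oxidation, rose from 19.3 ± 6.51 to 98.8 ± 20.8 CPM among 19 lipid storage and fatty acid oxidation genes. Dgat2, of the same list, read 246 and 648 (adjusted p = 0.0808). Mfge8, a bridge between dying cells and phagocytes, rose from 14.7 to 73.4 CPM among 21 efferocytosis genes, whose list test pointed downwards (adjusted p = 0.0879). The alveolar identity list did not pass: 0 of 28 genes were called, and 3 rose and 2 fell over the list alone (adjusted p = 0.213, and adjusted p = 0.559 with an estimated correlation). Among them, Fabp4 read 110 and 35 CPM (adjusted p = 0.181), Olr1 615 and 321 (0.122), Ctsk 315 and 519 (0.117) and Slc39a2 133 and 233 (0.107).

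In Kupffer cells, the macrophages of the liver sinusoids, most of the called changes lay in genes of B cells. Transcripts of the B cell receptor component Cd79a, of the B lineage transcription factors Ebf1 and Pax5, of IgD (Ighd) and of the follicular homing receptor Cxcr5 were lower in KO. No gene was called as higher, and no gene of the Kupffer identity list was called. Of 19085 genes, 12 fell, 4 of them immunoglobulin genes, and 1325 had an unadjusted p under 0.05. All 12 had non-overlapping groups, which chance gives for 10% of all genes and which a call itself makes likely. The count was 0 without WT replicate 1, 2 or 3, 1 without KO replicate 1, 4 without KO replicate 3 and 15 without KO replicate 2. It was 0 once immunoglobulin, T cell receptor and B lineage genes were removed. That alternative was added after the data were seen, and the genes it removed included Chst3 and Il5ra, which are on no B cell list fixed beforehand. Other tools called 413 (DESeq2) and 1 (voom), and the replicate block 0.

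Ebf1 (chromosome 11, 44617317 to 45008091) went from 21.2 ± 9.26 CPM to 0, at least 1320-fold lower (adjusted p = 0.034), and Pax5 (chromosome 4, 44524757 to 44710487) from 6.18 to 0, at least 386-fold lower. Fcmr fell from 55.1 ± 11.4 to 0.0662 CPM (832-fold; adjusted p = 0.00903) and Cd79a (chromosome 7, 24897381 to 24902197) from 105 ± 23.7 to 0.196 (537-fold; adjusted p = 0.0283). Ighd fell from 93 ± 10.6 to 0.88 ± 0.529 (106-fold; adjusted p = 0.00903). Chst3, a chondroitin sulfotransferase, fell from 15.6 ± 6.26 to 0.0627 CPM (adjusted p = 0.0187), Cxcr5 from 20.8 to 1.13 (18.5-fold) and the B cell kinase Blk from 17.8 ± 2.5 to 1.2 (14.9-fold). Il5ra, a subunit of the interleukin-5 receptor and chosen after its values were seen, went from 3.52 to 0.00558 CPM.

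Of 39 lists tested in Kupffer cells, 6 passed, 2 upwards and 4 downwards, and 0 with an estimated correlation, where the smallest adjusted p was 0.13, while fry called 1. B cell markers were lower as a group, with 5 of 15 falling and 14 adjusted over the list alone (median log2 −6.71; adjusted p = 3.15e-29, and adjusted p = 0.13 with an estimated correlation). Endothelial markers were shifted downwards with all 16 below 0 and 0 called in either count (median log2 −0.71; adjusted p = 3.89e-06, and adjusted p = 0.922 with an estimated correlation). Their summed level was 8390 CPM in WT and 5400 in KO, with Cldn5 at 97.3 and 43 (adjusted p = 0.482) and Lyve1 at 151 and 97.8 (0.557). Cell cycle genes were shifted upwards with 0 called of 29 and 2 rising over the list alone (median log2 0.44; adjusted p = 2.4e-07, and adjusted p = 0.667 with an estimated correlation). The mitotic genes Tpx2 and Cenpe read 9.93 and 26.2 CPM (adjusted p = 0.114) and 5.38 and 14.6 (0.245). Type I interferon response genes were shifted downwards with 0 called of 27 and 1 falling over the list alone (median log2 −0.35; adjusted p = 3.87e-07, and adjusted p = 0.667 with an estimated correlation). Oasl1 read 162 and 68.3 CPM (adjusted p = 0.114) and Rsad2 140 and 83.6 (0.406). Dissociation stress and immediate early genes, with 0 of 21 called in either count, were lower (median log2 −0.43; adjusted p = 0.000171, and adjusted p = 0.922 with an estimated correlation; 0.19 without WT replicate 3). Nr4a1 read 889 and 338 CPM (adjusted p = 0.425) and Hspa1a 2080 and 1060 (0.545). T and NK cell markers were shifted upwards with 0 of 16 called (adjusted p = 0.0159, and adjusted p = 0.922 with an estimated correlation; 0.25 without KO replicate 1, 0.115 without KO replicate 2 and 0.238 without WT replicate 3). Gzma read 30.3 and 48.8 CPM (adjusted p = 0.442) and Cd8a 14.2 and 29.3 (0.545). The Kupffer identity list did not pass (24 tested, 0 called, adjusted p = 0.789, and adjusted p = 0.981 with an estimated correlation).

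In microglia, the macrophages of the brain, no gene was called by edgeR among 17880 tested. An unadjusted p under 0.05 was reached by 794 genes, less than the share of 0.05 that chance alone gives on average. DESeq2 called 93 and voom called 1. The microglial identity list did not pass (25 tested, 0 called, adjusted p = 0.707, and adjusted p = 0.811 with an estimated correlation). B cell markers, which were far lower in the other 3 tissues' KO libraries, summed to 647 ± 65.5 CPM in WT and 609 ± 89.7 in KO microglia, and their list did not pass (6 tested, adjusted p = 0.741). WT replicate 2 stood apart from the other 5 microglial libraries, with 20646 genes at 10 or more counts against 17220 to 18198 and 0.32% of counts in mitochondrial genes against 0.13% to 0.18%. Without it edgeR called 1 gene and 2 lists.

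Of 36 lists tested in microglia, 4 passed, 2 upwards and 2 downwards, and 0 with an estimated correlation, where the smallest adjusted p was 0.204, while fry called 1. Lists numbered 1 without KO replicate 1, 1 without KO replicate 2 and 2 without WT replicate 2. Neutrophil markers were shifted upwards, with 0 of 6 called and 3 rising over the list alone (median log2 3.82, adjusted p = 4.76e-06, and adjusted p = 0.204 with an estimated correlation). Their summed level differed little, at 748 CPM in WT and 784 in KO. S100a8, S100a9 and Camp, at a very low level in WT, read 0.051 and 2.14 CPM (adjusted p = 0.491), 0.0317 and 2.26 (0.491) and 0.0131 and 0.681 (0.688). Monocyte markers (10 tested, 0 called) were shifted upwards (adjusted p = 0.0421, and adjusted p = 0.811 with an estimated correlation; 0.217 without KO replicate 1, 0.0789 without KO replicate 2 and 0.356 without WT replicate 1). Ms4a4c read 0.261 and 1.4 CPM (adjusted p = 0.987). Cytosolic ribosomal proteins were shifted downwards with 0 of 32 called (median log2 −0.24; adjusted p = 0.00925, and adjusted p = 0.811 with an estimated correlation). Rpl30 read 36.1 and 25.4 CPM and Rpl10a 103 and 83.5 (both adjusted p = 0.987). The call of the ribosomal list was lost without KO replicate 1 (0.217) or 2 (0.0789), and its direction turned without WT replicate 2 (0.539). Oxidative phosphorylation genes, with 0 of 24 called, were shifted downwards (median log2 −0.22; adjusted p = 0.0421, and adjusted p = 0.811 with an estimated correlation), a call lost without KO replicate 1 (0.377), 2 (0.0791) or 3 (0.0948) or WT replicate 2 (0.763). Sdhb, a subunit of succinate dehydrogenase, had a log2 fold change of −0.29 (adjusted p = 0.987).

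In splenic macrophages, which clear aged red cells and sit among lymphocytes, the loss of B cell transcripts was accompanied by a rise of neutrophil granule genes. Ltf and Ngp, proteins of neutrophil granules, rose, as did Bmpr1a (6.29-fold) and Arc, an immediate early gene (5.75-fold). Genes of B cells such as Pax5, Ebf1, Cd79a and Cr2 fell, together with Mef2c, a transcription factor of lymphoid and myeloid cells, and complement C3. Of 17808 genes, 133 were called, 23 higher and 110 lower in KO, 46 of them immunoglobulin genes, and 2079 had an unadjusted p under 0.05. All 133 had non-overlapping groups, which chance gives for 10% of all genes and which a call itself makes likely. The count was 18 without WT replicate 2, 38 without KO replicate 2, 44 without WT replicate 1, 46 without KO replicate 1, 55 without KO replicate 3 and 90 without WT replicate 3. It was 58 (23 higher and 35 lower) once immunoglobulin, T cell receptor and B lineage genes were removed. DESeq2 called 903 and the replicate block 10.

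Bmpr1a (chromosome 14, 34410734 to 34503341) rose from 3.27 ± 0.436 to 20.5 ± 5.03 CPM in splenic macrophages (6.29-fold; log2 2.68 ± 0.24; adjusted p = 0.00805). Arc (chromosome 15, 74669083 to 74672570) rose from 21.7 ± 3.65 to 125 ± 5.45 CPM (adjusted p = 0.00403). Dbn1, an actin-binding protein, rose from 1.05 to 10.9 CPM, G0s2, an inhibitor of lipolysis, from 1.52 to 11.5, and Xcr1, the chemokine receptor of type 1 dendritic cells, from 4.1 to 20 (adjusted p = 0.032). Among the falls, Mef2c went from 68.5 ± 17.6 to 6.17 ± 0.939 CPM (log2 −3.43 ± 0.23; adjusted p = 0.00403), Scd1 from 74.7 to 10.6 (adjusted p = 0.0106) and C3 from 181 ± 58.2 to 50 ± 1.9 (adjusted p = 0.0157). Mef2c, Scd1 and C3, like Il5ra in this cell type, were chosen after their values were seen. Slco4a1, an organic anion transporter, went from 9.59 ± 8.54 CPM to 0, at least 544-fold lower, with a WT spread close to its mean (adjusted p = 0.0463). Among the genes described for this cell type, Pax5, Ebf1, Cr2, Cd79b, Ighd, Arc and Mef2c kept their call whichever library was left out.

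Of 39 lists tested in splenic macrophages, 11 passed, 7 upwards and 4 downwards, and 0 with an estimated correlation, where the smallest adjusted p was 0.0521, while fry called 2. Lists numbered 7 without WT replicate 3. B cell markers fell as a group, 14 of 15 over all genes and 15 adjusted over the list alone (median log2 −6.68; adjusted p = 4.93e-28, and adjusted p = 0.0521 with an estimated correlation). Cd79a, at 0.656 CPM in KO, was 252-fold lower. Fcer2a went from 56.2 to 0.593, Cr2 from 60 to 1.83 and Cd79b from 105 to 27.9 CPM. Pax5 went from 9.14 CPM to 0, at least 519-fold lower, Il5ra from 4.78 to 0, at least 271-fold lower, and Ebf1 from 32.6 ± 8.9 to 0.017 CPM. Fcmr, Ighd and Ly6d, a surface protein of early lymphoid cells, fell from 98 ± 33.2 to 0.335, from 130 to 0.586 and from 73.8 to 0.58 CPM. Neutrophil markers rose as a group, 5 of 14 over all genes and 11 adjusted over the list alone with 0 falling (median log2 2.45; adjusted p = 4.88e-13, and adjusted p = 0.0646 with an estimated correlation). Their summed level was 227 CPM in WT and 796 in KO. Ltf rose from 25.5 ± 8.61 to 167 ± 33.9 CPM (adjusted p = 0.0106), Ngp from 29.3 ± 15.7 to 194 ± 36.7 (0.0345), Lcn2 from 4.42 to 29.7 (0.0448), S100a9 from 23.3 to 107 (0.0143) and S100a8 from 17.6 to 78.1 (0.042).

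The lists of cell cycle genes and of erythroid markers were shifted upwards in the splenic libraries with the preset correlation alone, and few or none of their members were called. Cell cycle genes were shifted upwards with 1 of 29 rising and 24 adjusted over the list alone (median log2 1.22; adjusted p = 4.88e-13, and adjusted p = 0.741 with an estimated correlation). Their sum was 1050 CPM in WT and 1940 in KO. Kif11, a mitotic kinesin, rose from 11.9 to 35.6 CPM (adjusted p = 0.0386), while Rrm2 read 71 and 203 (adjusted p = 0.0981). Erythroid markers had 0 called of 13 and 5 rising over the list alone (median log2 1.21; adjusted p = 2.07e-06, and adjusted p = 0.741 with an estimated correlation). Car1 read 27.4 and 81.9 CPM (adjusted p = 0.084) and Gata1 7.71 and 33.9 (0.169). Platelet and megakaryocyte markers had 0 called of 10 and 1 rising over the list alone (median log2 0.79; adjusted p = 0.00323, and adjusted p = 0.615 with an estimated correlation). Gp9 had a log2 fold change of 1.63 (adjusted p = 0.168). T and NK cell markers had 1 of 16 rising and 2 over the list alone (adjusted p = 0.00799, and adjusted p = 0.778 with an estimated correlation; 0.205 without KO replicate 1, 0.108 without WT replicate 2 and 0.1 without WT replicate 3). The called member was Cd8a, from 6.04 to 25 CPM (adjusted p = 0.049; not called with DESeq2 size factors), which is carried by T cells and also by some dendritic cells. Gzmb had a log2 fold change of 1.90 (adjusted p = 0.175). Dissociation stress and immediate early genes had 0 called of 21 and 7 rising over the list alone (median log2 0.45; adjusted p = 0.000121, and adjusted p = 0.741 with an estimated correlation). Egr1 read 1750 and 4020 CPM (adjusted p = 0.0834) and Junb 3600 and 5430 (0.0966). Inflammatory cytokines and chemokines had 0 called of 24 in either count (median log2 0.56; adjusted p = 0.0178, and adjusted p = 0.778 with an estimated correlation), a call lost without KO replicate 2 (0.461), WT replicate 2 (0.108) or WT replicate 3 (0.242). Ccl5 and Nfkbiz had log2 fold changes of 1.02 (adjusted p = 0.126) and 0.78 (0.243).

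MHC class II, respiratory chain and ribosomal genes were shifted slightly downwards in splenic macrophages. MHC class II presentation had 1 of 15 falling and 2 over the list alone (adjusted p = 0.027, and adjusted p = 0.778 with an estimated correlation; 0.372 without KO replicate 3 and 0.266 without WT replicate 1). The called member was H2-DMb2, a chain of the peptide-loading factor, from 125 ± 41.1 to 31.4 ± 3.18 CPM (adjusted p = 0.0131), and H2-Ob, a gene of B cells, read 103 and 26.8 (adjusted p = 0.0608). Oxidative phosphorylation had 0 called of 24 (adjusted p = 0.0239, and adjusted p = 0.778 with an estimated correlation; 0.312 without KO replicate 1, 0.0869 without KO replicate 2, 0.0809 without WT replicate 1 and 0.106 without WT replicate 3). Cytosolic ribosomal proteins had 0 called of 32 (adjusted p = 0.00441, and adjusted p = 0.778 with an estimated correlation; 0.231 without KO replicate 1, 0.0809 without WT replicate 1 and 0.0891 without WT replicate 3). Ndufb8 and Rpl12 had log2 fold changes of −0.44 (adjusted p = 0.316) and −0.45 (0.375). Dendritic cell markers did not pass as a list (17 tested, 1 rising and 1 falling, 4 and 2 over the list alone, adjusted p = 0.163), with Xcr1 rising and Ly6d falling. The splenic identity list did not pass (20 tested, 0 called, adjusted p = 0.965, and adjusted p = 0.978 with an estimated correlation).

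**Figure D3:**
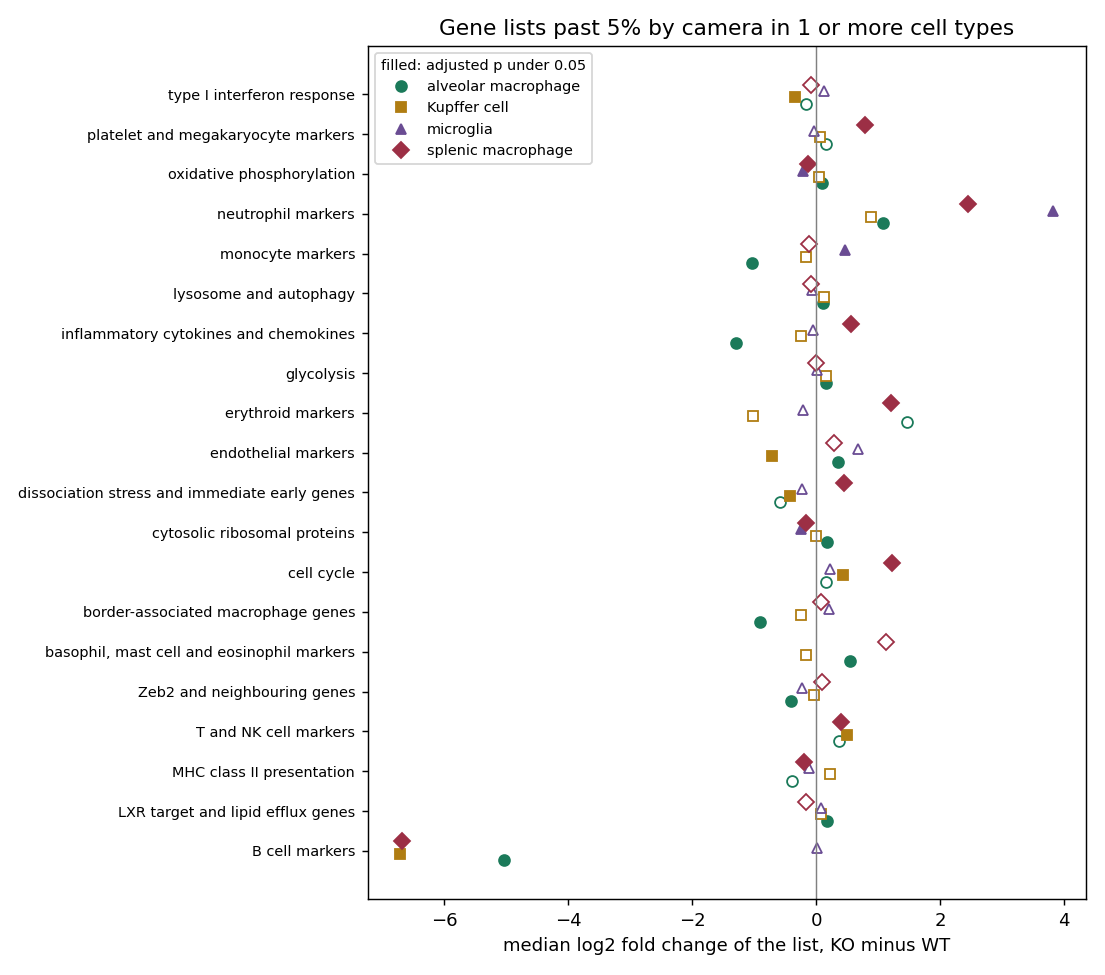
Median log2 fold change of KO over WT (horizontal axis; genes at 0 in a genotype set to their bound) for the lists past an adjusted p of 0.05 by camera in at least 1 cell type; symbols are cell types, filled where the list passed. B cell markers lie at −5.04, −6.71 and −6.68 in alveolar, Kupffer and splenic libraries, and neutrophil markers at 1.07, 3.82 and 2.45 in the alveolar, microglial and splenic libraries in which they passed.

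The level of B cell transcripts was then compared over the 4 tissues. The 15 B cell markers summed to 121 ± 45.3 CPM in WT and 9.23 ± 0.42 in KO alveolar macrophages (13.1-fold), to 972 ± 234 and 98.2 ± 39.3 in Kupffer cells (9.9-fold). They summed to 1540 ± 326 and 87 ± 27.9 in splenic macrophages (17.7-fold) and to 647 ± 65.5 and 609 ± 89.7 in microglia (1.06-fold). Immunoglobulin variable segments, which each B cell clone rearranges differently, were counted when they held 10 or more counts, out of 218. They numbered 142.3 ± 14.2 in WT and 2.7 ± 3.1 in KO Kupffer libraries, 148.3 ± 3.5 and 7.7 ± 7.4 in splenic libraries. Alveolar libraries held 40 ± 7.8 and 1.7 ± 1.5, and microglial libraries 5 ± 4.4 and 0.7 ± 0.6. Ighm made up most of the microglial sum in both genotypes (587 CPM in WT and 560 in KO).

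**Figure D4:**
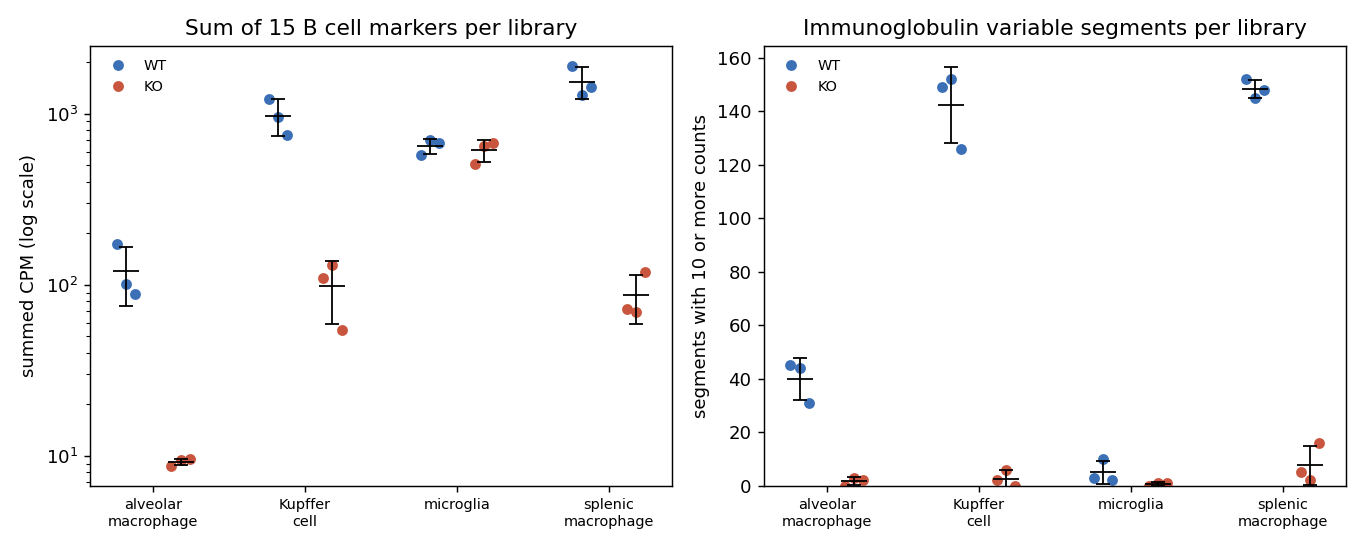
Left, summed CPM of 15 B cell markers per library (log axis), and right, immunoglobulin variable segments with 10 or more counts per library (linear axis), by cell type and genotype; points are libraries, horizontal lines means and bars SD of 3 libraries. In splenic libraries the WT sums lie at 1280 CPM and above and the KO sums at 119 and below, while the microglial sums overlap. Microglial segments number 2 to 10 in WT and 0 to 1 in KO.

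Genes called in more than a single cell type were mostly B cell genes. Kupffer cells and splenic macrophages shared 9 lower genes, of 12 and 108 among 16750 tested in both, where independent lists of these sizes would share 0.077 (one-sided Fisher's exact test, p = 2.97e-18). Alveolar and splenic macrophages shared 4 lower genes of 18 and 66 (0.075 for independent lists; Fisher's exact test, p = 8.23e-07) and 1 higher gene of 23 and 19, Bmpr1a (0.028 for independent lists; Fisher's exact test, p = 0.0274). Alveolar macrophages and Kupffer cells shared 1 lower gene (0.012 for independent lists). Fisher's test takes genes as independent, while transcripts of B cells can move together as a block. Its p-values for the lower genes therefore do not measure how well the tissues agree. In all, 13 genes were called in at least 2 cell types, and Fcmr was called in 3. Cd79a, Il5ra, Pax5, Blk, Ebf1 and Ighd were called in Kupffer and splenic libraries, and Fcer2a and Ighm in alveolar and splenic libraries.

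A single model of all 24 libraries asked for which genes the mean effect over the 4 cell types differed from 0. A change in some of the types alone can also give such a mean. The mean effect over the 4 types was called for 150 of 24030 genes, 37 higher and 113 lower in KO, 23 of them immunoglobulin genes. Ighd (mean log2 −4.44 ± 0.36; adjusted p = 1.7e-06), Cd79a (−5.74 ± 0.52; 5.87e-06), Ighm (−2.38 ± 0.21; 5.87e-06) and the B cell antigen Ms4a1 (adjusted p = 1.43e-05) were among the 10 genes with the smallest p. Siglecg, an inhibitory lectin of B cells, and Tnfrsf13b, a receptor for the B cell factors BAFF and APRIL, had means of −2.18 ± 0.23 and −1.20 ± 0.12. In microglia Ighd, Cd79a, Ighm and Siglecg had log2 fold changes of 0.09, −0.26, −0.06 and 0.15, while Ms4a1 read 0.451 CPM in WT and 0.0132 in KO. Tnfrsf13b had −0.04 in alveolar macrophages and −0.21 in microglia. Bmpr1a was the higher gene among these 10, with a mean log2 fold change of 1.39 ± 0.10 (adjusted p = 5.41e-07). It read 17 CPM in WT and 27.4 in KO Kupffer cells (adjusted p = 0.217) and 15.2 and 19.8 in microglia (adjusted p = 0.987). Its 4 log2 fold changes in the single model were 1.75 (alveolar), 0.72 (Kupffer), 0.39 (microglial) and 2.69 (splenic).

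The same model asked which effects differed between the cell types. The interaction was called for 126 genes, 58 of which were also called for the mean effect, and 2780 had an unadjusted p under 0.05. Without alveolar WT replicate 2 the count was 74, and with the replicate block it was 61. Chn2, a GTPase-activating protein for Rac, stood at 1.48 CPM in WT and 0.011 in KO alveolar macrophages, against log2 fold changes of 0.52 ± 0.20, 0.27 ± 0.19 and 0.08 ± 0.19 in Kupffer cells, microglia and splenic macrophages (interaction adjusted p = 2.83e-07). Cd37, a tetraspanin of B cells and other leukocytes, went from 95.2 to 10.1 CPM in splenic macrophages (log2 −3.18 ± 0.21) and from 47.7 to 66.6 in alveolar macrophages (0.52 ± 0.20; interaction adjusted p = 5.81e-06). Adgre4, near absent from KO alveolar macrophages, was abundant in Kupffer cells (549 CPM in WT and 629 in KO) and splenic macrophages (1180 and 1020, interaction adjusted p = 0.000454). It read 9.7 CPM in WT alveolar macrophages. Whether low WT alveolar levels such as this and that of Chn2 came from carried-over cells was not tested. Slc16a1 and Basp1 had alveolar log2 fold changes of −2.35 and 2.62, against −0.52 and 0.31 in Kupffer cells, 0.60 and −0.11 in microglia and 0.90 and −0.16 in splenic macrophages (interaction adjusted p = 0.000363 for both). Grap, an adaptor protein, went from 5.52 to 24.4 CPM in alveolar macrophages and from 24.8 to 8.88 in splenic macrophages (interaction adjusted p = 0.000246).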

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

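The tests of variable segments, of depth, of the 3 accounts of the alveolar Zeb2 difference and of neutrophils as the source of Cxcr2 were chosen only after the results were seen; the counts over other splits of the samples were planned.

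Other splits of the same libraries were fitted as the real one. For each cell type the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 55 genes in alveolar macrophages (highest other 0; 1 of 10 splits as large), 12 in Kupffer cells (highest other 0; 1 of 10), 133 in splenic macrophages (highest other 0; 1 of 10) and 0 in microglia (highest other 0; 10 of 10). For lists it gave 13 in alveolar macrophages (highest other 9; 1 of 10), 11 in splenic macrophages (highest other 9; 1 of 10) and 4 in microglia (highest other 4; 2 of 10). In Kupffer cells it gave 6 lists while another split gave 16 and 9 of 10 splits gave at least 6. A structure of these samples other than genotype and genes that move together within lists could both give this, and 0 Kupffer lists passed with an estimated correlation (smallest adjusted p = 0.13). No other drawn split called as many genes for the WT cell types (11331 genes, highest other 1599, 1 of 50 splits as large). The same held for the interaction (126, highest other 93, 1 of 25) and the common effect (150, highest other 39, 1 of 25). These shares were under 0.05, the limit set beforehand. For the interaction, another split came close. Those splits reassign the genotype within each cell type, so they ask about any genotype effect and not whether it differs between types.

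The loss of B cell transcripts from splenic, Kupffer and alveolar libraries stood out because the effect differed between cell types in interaction tests of B cell genes with values below 0 in these 3: Ighd (0.000814), Ighj1 (0.00139), Siglecg (0.00721), Ebf1 (0.0119), Ighm (0.0144), Cd79a (0.0151) and Cr2 (0.0283). Depth was excluded as the cause, since the summed counts of B cell markers differed 17-fold between splenic WT and KO while the totals of any cell type differed by at most 1.23-fold. Fewer B cells carried through the sort would take away rearranged variable segments together with the markers. WT splenic libraries held 19.3 times as many such segments as KO libraries, but 40 of the 122 tested were themselves among the called genes, so this count restates the loss and does not decide its source. A lower number of B cells in the KO tissues, of which a few pass a macrophage gate, is a candidate explanation that stays open; Zeb2 acts in blood cell formation, and a B cell effect of the allele is a biological hypothesis that counts of sorted macrophages do not test. A smaller carry-over for technical reasons, such as sorting on different days, stays open because the labels give no sorting day or gate.

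The lower Zeb2 of alveolar macrophages, which was not called by edgeR (adjusted p = 0.116), was weighed because Zeb2 is the gene of the title. Loss of carried-over B cells was excluded: splenic libraries lost more B cell transcripts, yet the lower bound of their Zeb2 log2 fold change was −0.13, where losing as many CPM as the alveolar libraries (121) would give −0.71. Loss of carried-over macrophages of the other 3 types was excluded too, since they would have to make up at least 38.9% to 46.6% of the WT cells, by type, and bring at least 11.6 times the Maf of the highest WT alveolar library (21.7 to 45.8 against 1.86 CPM). Loss of carried-over monocytes cannot be told apart from a change inside the macrophages. Monocyte markers were lower too (median log2 −1.04), and no library here gives the Zeb2 level of monocytes. For dendritic cells the markers do not decide, since their list had a median log2 of 0.07 and a mean of −0.71. An effect of the allele on Zeb2 in alveolar macrophages themselves may account for the value and stays a hypothesis.

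The rise of Cxcr2 in alveolar macrophages (91.9 CPM gained) was weighed because Cxcr2 is a neutrophil marker. S100a8 and S100a9 together gained 1.08 CPM for each CPM of Cxcr2 there and 32.8 in splenic libraries, which argues against neutrophils like those of the splenic gain. Of the 12 other neutrophil markers tested in alveolar libraries, however, 11 had values above 0 (median log2 1.07), and no library here gives the profile of lung neutrophils. More neutrophils carried through the sort thus cannot be told apart from a change of Cxcr2 within alveolar macrophages, which stays a hypothesis.

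The other results below were listed because an interaction test found that the genotype effect differed between cell types; fitted log2 fold changes are in the order alveolar, Kupffer, microglial and splenic, with the adjusted p of the interaction. Chn2 (2.83e-07) had 0.52, 0.27 and 0.08 outside the alveolar libraries, where KO held 0.011 CPM against 1.48 in WT. Hic1 (0.000246) and Cacnb1 (0.000426) had 0.0055 and 0.00592 CPM in alveolar KO against 1.84 and 1.41 in WT, and −0.49, 1.60 and 0.89, and 0.30, −0.42 and −0.69, in the other types. Adgre4 (0.000454) had −8.05, 0.23, −1.01 and −0.17. For Chn2, Hic1, Cacnb1 and Adgre4, low in WT alveolar libraries, a loss of carried-over cells was not tested. Lower in alveolar macrophages alone among the calls within a cell type were Slc16a1 (0.000363; −2.35, −0.52, 0.60, 0.90), Ms4a6c (0.000454; −2.11, 0.06, −0.10, −0.46), Gpd1 (0.0131; −3.54, −0.15, −0.36, −0.17), Emilin1 (0.0336; −3.76, −0.54, 0.47, −0.99) and Arhgap15 (0.00676; −2.27, 0.13, 0.72, −0.39). Inka1 (0.000426) had −2.84, 0.18, −0.06 and 0.24. Basp1 (0.000363) and Cd63 (0.000608) had 2.62, 0.31, −0.11 and −0.16, and 2.26, −0.16, −0.41 and 0.74. Bmpr1a (0.00062) was above 0 in all 4 types, with 1.75, 0.72, 0.39 and 2.69. Grap (0.000246) had 2.17 in alveolar and −1.43 in splenic libraries. Scd1 (0.00421) had 1.59, −0.39, 2.24 and −2.77, C3 (0.00926) 0.65, 0.05, 2.46 and −1.81, and Slco4a1 (0.0238) 1.25, 0.08 and 0.08 before falling to 0 counts in splenic KO. Among genes that B cells share with other leukocytes, Cd37 (5.81e-06) had 0.52, −0.47, −0.24 and −3.18, Tnfrsf13b (0.000246) −0.04, −1.16, −0.21 and −3.37, Mef2c (0.0132) −1.10, −1.53, 0.05 and −3.42, and H2-DMb2 (0.0333) −0.31, −1.10, 0.03 and −1.94. Of the B cell genes above, Siglecg had −1.77, −2.83, 0.15 and −4.28, and Ighm −3.31, −2.59, −0.06 and −3.58. In microglia, Ighd, Ebf1 and Cr2 had 0.09, 1.30 and 0.84.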

How the results depend on the processing

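The alternative without B lineage genes was chosen after seeing the data. The count of called genes moved most: over the 4 cell types 26 of 64 values stayed within 1.5 times the reported count and 38 did not, and for gene lists 28 of 40 did. The number of genes differing between WT cell types (9767 to 12768) stayed within that limit in all 18 alternatives. Within cell types, single named genes kept direction and side of the threshold in 1301 of 1752 values, lost a call in 366, gained one in 82 and turned in 3. The 67 calls of named genes held in 65 cases with DESeq2 size factors, 67 with upper-quartile scaling, 67 with the stricter filter, 67 with DESeq2, 47 with voom, 5 with the replicate block and 121 of 402 when 1 library was left out, none turning direction. Single lists kept their call in 234 of 340 values. Scaling never moved the share of higher calls by over 10 percentage points. Adjusted p-values that DESeq2 gives as NA yield no value. At this depth a gene at 0 in 3 libraries has a level below about 0.0169 CPM (alveolar KO). Among genes above 5 CPM, 2-fold changes are missed more often than not, as the simulation shows.

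By setting, the counts of genes were as follows; fewer or more genes enter under other filters, and otherwise the cause was not tested. No filter gave 163 (alveolar), 76 (Kupffer), 13 (microglia) and 330 (splenic), and the stricter filter 95 (alveolar) and 35 (Kupffer). DESeq2 gave 922, 413, 93 and 903, 957 for the interaction and 639 for the common effect, voom 1 (Kupffer) and 1 (microglia), and the 1.5-fold threshold 21 (alveolar). All 24 libraries in a single fit gave 297 (alveolar), 48 (Kupffer) and 19 (microglia). Removing B lineage genes gave 0 (Kupffer) and 58 (splenic). An estimated correlation left 0 lists in all 4 cell types, and fry left 1 (Kupffer), 1 (microglia) and 2 (splenic). Zeb2 in alveolar macrophages, −0.89 with DESeq2 and −0.89 with all 24 libraries, was called in both.

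With the replicate number as a block, 0 genes were called in alveolar macrophages, 0 in Kupffer cells and 10 in splenic macrophages, and the interaction gave 61; of lists, that of Zeb2 and genes near it in alveolar macrophages (adjusted p = 0.0772) and MHC class II in splenic macrophages (0.0713) lost their call. Deviations of libraries with the same number correlated at −0.35 to 0.30 over 12 pairs of KO and WT. Between cell types within a genotype they correlated at −0.23 to 0.30. The KO library correlated best with its own number only for microglial KO replicate 1 and splenic KO replicate 3. With 3 libraries in a group, these values do not exclude a shared animal or sorting day. The block leaves fewer residual degrees of freedom, and a lost call is not read here as a weaker effect.

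Leaving out 1 library gave 0 to 29 genes in alveolar macrophages, 0 to 15 in Kupffer cells, 0 to 1 in microglia and 18 to 90 in splenic macrophages, 74 (without alveolar WT replicate 2) to 159 for the interaction and 104 to 176 for the common effect. Lists ranged over 9 to 13, 4 to 10, 1 to 5 and 7 to 10 in the same order. The Zeb2 log2 fold change ranged from −1.07 to −0.78 (alveolar), −0.14 to 0.09 (Kupffer; 0.08 without KO replicate 2 and 0.09 without WT replicate 2), −0.12 to 0.36 (microglia; −0.01 without KO replicate 1 and −0.12 without WT replicate 2) and 0.06 to 0.12 (splenic). In Kupffer cells Zeb2os turned to −0.05 with voom and −0.20 without KO replicate 3 (range −0.20 to 0.34), and Arhgap15 to −0.01 without KO replicate 2 (range −0.01 to 0.30). The microglial ribosomal list turned without WT replicate 2 (adjusted p = 0.539; range 0.000833 to 0.539). None of these turned values was called.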

Other observations

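The genes described here were chosen after their values were seen, and the tests of the added dendritic cell lists had their predictions written before those lists were tested. Of the dendritic cell genes looked at, Xcr1 and Cd209a passed for the common effect, in opposite directions. Xcr1, the chemokine receptor of type 1 dendritic cells, had a mean log2 fold change of 1.28 ± 0.26 (SE) over the 4 cell types (adjusted p = 0.0233; 0.0514 without Kupffer WT replicate 1) and stood at 16.5 CPM in WT and 67.7 in KO Kupffer cells (adjusted p = 0.196). Cd209a, a lectin of type 2 and monocyte-derived dendritic cells, was lower in KO for the common effect (adjusted p = 0.00195; 1 without microglial WT replicate 2), with 1 alveolar KO read and none in microglial KO, and stood at 37.8 and 0.585 CPM in Kupffer cells (adjusted p = 0.139). The other dendritic cell genes looked at did not pass for the common effect: Clec9a (adjusted p = 0.0855), Itgae (0.264), Cd8a (0.383), Mgl2 (0.715) and Clec10a (1).

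The hypothesis that type 1 and type 2 dendritic cell genes each move with genotype was tested with 2 further lists. All 13 type 1 genes were tested, and their list was shifted upwards in the mean effect over the 4 cell types. Camera gave p = 2.25e-06, and p = 0.000313 with an estimated correlation. The median log2 was 0.23, and Naaa was the called member. All 12 type 2 genes were tested, and their list was shifted downwards. Camera gave p = 0.033, and p = 0.133 with an estimated correlation. The median log2 was −0.36, and none was called. Both are shifts of a mean over the 4 cell types, which a change in some types alone can give. Of the genes looked at first, Xcr1, Clec9a and Itgae had log2 fold changes of 0.08, 0.12 and 1.82 in alveolar libraries, against 2.05, 1.09 and 1.44 in Kupffer cells. Mgl2 had −2.41 and −3.31 in these types, and 0.74 in splenic libraries, at a very low level. More type 1 and fewer type 2 dendritic cells among the sorted cells of some KO tissues could give such values, the latter only with the preset correlation. Macrophages expressing some of these genes themselves were not excluded.

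In alveolar macrophages, Myo1d and Tmem98, adjacent on chromosome 11, both rose. Cxcr1, a second receptor for neutrophil-attracting chemokines, read 8.7 ± 1.34 CPM in WT and 35.3 ± 10.3 in KO beside Cxcr2. Tnf spread widely in WT alveolar libraries (646 ± 818 CPM, against 50.9 ± 19.2 in KO) and was not called. Microglial libraries held 587 CPM of Ighm in WT and 560 in KO with few variable segments in either (5 ± 4.4 and 0.7 ± 0.6 with 10 or more counts), unlike the WT splenic libraries (148.3 ± 3.5).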
